A study of Homo sapiens with 96 samples.

How the data were processed

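Gene expression was measured on Affymetrix HG-U133 Plus 2.0 arrays, 1 array per sample, in frozen surgical tissue from patients with malignant pleural mesothelioma, a cancer of the lining of the chest cavity. The 96 samples formed 3 groups by their labels: 41 samples of non-tumour lung, 41 tumours that share a patient number with those lungs, and 14 tumours without a lung sample. The deposited table holds 1 log2 expression value per probe set and array, for 54675 probe sets. Per the submitters' processing notes the values were made with GCRMA, a background correction and quantile normalization for these arrays, with no version given. Background settings and any filter are not given in the sources used here. GCRMA usually leaves a heap of equal low values, and none was seen here, so the exact background step stays open. The deposited log2 values ran from 3.91 at the lowest to 15.6 at the highest. Scanner files and detection calls were not used here, so no background level or detection limit per probe set was set. For arrays, precision is limited by the number of samples in each group.

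Probe sets were named through the platform annotation, with symbols updated through Entrez identifiers. Of the 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were unnamed here. Among the probe sets with 1 symbol, 41043 were matched to a current symbol and 54 kept the older name. No gene was named from a probe set with several symbols, so some well known genes were not analysed here. The 59 probe sets of sex-linked donor-specific transcripts were left out of every test. A gene was represented by its probe set with the highest mean over all arrays, which gave 19740 genes. The planned filter, a log2 value above 4 in at least 20 arrays, removed 0 probe sets. The comparison without a filter therefore moved nothing, and a stricter planned filter (above 6 in at least 41 arrays) kept 43221 probe sets and 17530 genes.

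Tumours were compared with lungs in the 41 pairs by limma 3.58.1 in R 4.3.3, with the patient number as a block and empirical Bayes moderation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. The pairing comes from patient numbers that the labels share between groups and from the series' design text. Deviations from the group means of same-numbered samples had a median correlation of 0.249, against -0.00385 for samples with different numbers. After the width of each array's value distribution was regressed out, these medians were 0.0771 and -0.0102. Before that regression the same-numbered values ran from -0.542 to 0.777. Only 4 of 41 tumours correlated best with the lung of their own number, and 6 did after it. In 2 of the 41 pairs the lung and tumour arrays did not match on donor-specific transcripts. These pairs stayed in the fit, and the fit without them is among the alternatives.

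The 34 gene lists (cell types, pathways and disease genes) were fixed before the data were examined. They were tested in the paired fit with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry. Adjusted p-values for lists are Benjamini-Hochberg values over the 34 lists. The variability of each gene was compared between 55 tumours and 41 lungs by a limma fit of absolute deviations from the group median. A gene was called there at an adjusted p under 0.05 and a ratio of standard deviations of at least 1.5, or its inverse. The 14 tumours without a lung sample were compared with the 41 paired tumours in a limma fit with the thresholds used for the pairs.

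For 12 pairs of lists, the mean z-score of each list's genes was correlated across the 55 tumours, genes in both lists left out, with two-sided permutation p-values from 1e+05 resamples and Benjamini-Hochberg adjustment over the 12 pairs. A principal component analysis used the 2000 most variable genes of the 55 tumours. The rule for named genes was also fixed in advance. It took the 12 largest rises and the 12 largest falls among called genes that moved the same way in at least 37 of 41 pairs. From each list it took up to 3 called members in the direction most members took and up to 2 in the other direction. For variability it took the 10 highest and 5 lowest ratios among called genes, and for the leading component the 8 genes with the strongest correlation on either side. Other list members may be named with their values where they were not called.

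Arrays differed in the width of their value distribution, measured as the 90th percentile of all probe sets of an array. Arrays with a 90th percentile of at least 10 are called wide and the others narrow. This limit, and a limit of 10 on the mean of the skeletal muscle list, were chosen after the data were seen. The split by width cuts across lungs, paired tumours and further tumours, was shared in part by the 2 tissues of a patient (r = 0.685 over 41 pairs, rho = 0.589, permutation p = 2e-05 and 6e-05, 0.587 without 2 pairs), and its cause is open. The alternatives planned before the data were examined covered the block, the samples, the probe set rule, the filter, the normalization, array weights, the moderation, a Wilcoxon signed-rank test and limma's treat test. Alternatives added afterwards covered the array width, samples with skeletal muscle transcripts, the pairs that did not match, a filter at 7 in at least 20 arrays, and a random division of the lungs between 2 comparisons.

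The fits were tested on simulated log2 data for 19740 genes, with 200 changed genes. In the simulated paired comparison, 67 of 67 genes changed by 1.5 log2 units and 66 of 66 changed by 3 were called, with 1 unchanged gene called; 0 of 67 genes changed by 0.5 reached the threshold of size. In the simulated variability comparison, 64 of 66 genes with a 3-fold ratio, 38 of 67 with a 2-fold ratio and 3 of 67 with a 1.3-fold ratio were called, with 1 unchanged gene. In the simulated comparison of 14 with 41 tumours, 63 of 67 genes changed by 1.5 log2 units and 66 of 66 changed by 3 were called, as was 1 of 67 changed by 0.5, with 2 unchanged genes. All these counts describe the simulated data only. Of 99 regroupings of the real tumours into 14 and 41, 1 called 626 genes, and 0 with array width as a covariate. The simulated error rate and power for 14 against 41 tumours therefore cannot be carried over to arrays that differ in width. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.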

Results

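The series was made to find genes that differ between malignant pleural mesothelioma and non-tumour lung of the same patients, and differences among the tumours. RNA from 41 lungs, 41 tumours of the same patients and 14 further tumours was measured on 96 arrays. The arrays had similar centres, with medians of 7.39 ± 0.05 in lungs (SD, n = 41), 7.41 ± 0.07 in paired tumours (n = 41) and 7.38 ± 0.05 in the further tumours (n = 14), in log2 units. Their width varied more. The 90th percentile ranged from 9.49 to 10.3 in lungs and from 9.30 to 10.3 in paired tumours, and the 2 tissues of a pair differed by -0.04 ± 0.23 (SD of 41 differences, sign-flip permutation p = 0.276, two-sided). Wide arrays numbered 23 of 41 lungs, 25 of 41 paired tumours and 11 of 14 further tumours.

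Genes of differentiated lung were among the largest falls in tumour, and genes of matrix and of dividing cells, with the mesothelial marker WT1, among the largest rises. In the 41 pairs, 318 genes were higher and 844 lower in tumour, 1162 of 19740 genes tested by limma with the patient as a block. At the adjusted p alone, 4327 genes were higher and 3883 lower. Of the called genes, 714 moved the same way in at least 37 of 41 pairs. The median change of all genes was 0.02 log2 units. Among 710 called genes with several probe sets, 19 had a probe set past the adjusted p in the opposite direction. Under limma's treat test against a change of 1 log2 unit, 432 genes passed, 90 higher and 342 lower. Of the 34 gene lists 18 passed camera at its preset correlation and 1, alveolar type I markers, at an estimated correlation, so the matrix, mesothelial and cell division lists did not pass there.

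The largest falls were in alveolar and airway genes. AQP4, a water channel of alveolar epithelium, fell by 6.14 ± 0.31 log2 units (SE, 41 pairs), a 70.5-fold difference, and was lower in 41 of 41 tumours with a limma adjusted p of 1.7e-19. SCGB1A1, the secretoglobin of airway club cells, fell by 5.86 ± 0.40, lower in 40 pairs. CYP4B1, a cytochrome P450 abundant in lung, fell by 5.51 ± 0.29. SFTA3 fell by 5.82 ± 0.37, SFTA2 by 4.97 ± 0.29, SFTPB by 4.78 ± 0.31 and SFTPC by 4.37 ± 0.32; the last 2 encode surfactant proteins. WIF1, a secreted Wnt inhibitor, fell by 5.03 ± 0.34. EHF, an epithelial transcription factor, fell by 4.77 ± 0.29, and TMEM100, RTKN2 and CEACAM6 had changes of -4.64, -4.58 and -4.41.

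The 12 largest rises included genes of several lists. COL11A1, a fibrillar collagen chain, rose by 4.25 ± 0.38 log2 units, 19.1-fold, in 39 of 41 pairs, with a limma adjusted p of 2.1e-12. SPP1, which encodes osteopontin, rose by 3.91 ± 0.24 in 41 of 41 pairs. WT1, a transcription factor used as a mesothelial marker, rose by 3.86 ± 0.36. CTHRC1 rose by 3.65 ± 0.33, THBS2 by 3.20 ± 0.25, SULF1 by 2.54 ± 0.26 and SERPINE2, a protease inhibitor, by 2.84 ± 0.25. TOP2A, the topoisomerase of dividing cells, rose by 3.34 ± 0.23 in 41 of 41 pairs. ANLN and NDC80, which act in cytokinesis and at the kinetochore, rose by 2.78 ± 0.31 and 2.64 ± 0.22. TWIST1, a mesenchymal transcription factor, rose by 3.00 ± 0.27 and NMU, a neuropeptide, by 2.53 ± 0.34.

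**Figure D1:**
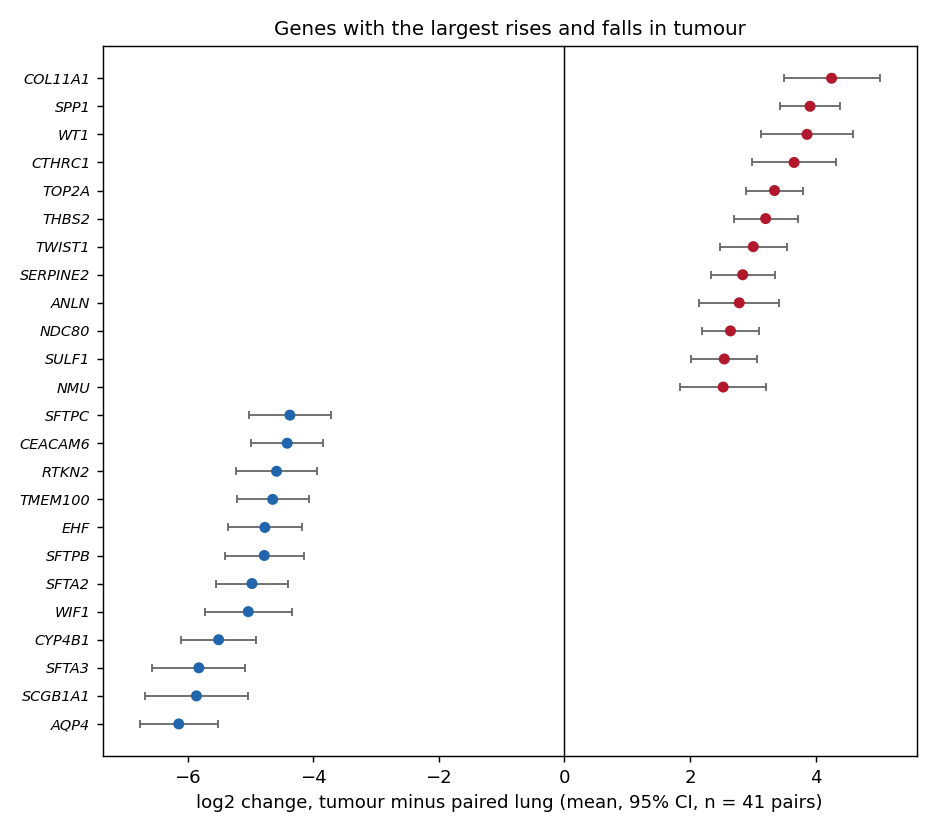
Log2 change in tumour minus paired lung for the 12 largest rises (red) and 12 largest falls (blue), with the mean and its 95% confidence interval over 41 pairs. The rises lie between 2.53 and 4.25 and the falls between -4.37 and -6.14 log2 units.

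Most markers of lung epithelium were lower in tumour. Of 13 measured alveolar type II cell markers 12 fell and 0 rose, with a list median of -3.18 log2 units; SFTPB, SFTPC and NAPSA, a protease that processes surfactant protein, fell by 4.78, 4.37 and 3.86. Of 12 alveolar type I markers 11 fell, with a median of -3.00, among them AQP4, RTKN2 and AGER at -6.14, -4.58 and -3.50. Of 14 airway markers 11 fell, with a median of -2.51; PIGR, the carrier of secreted immunoglobulin, fell by 4.24 ± 0.26, although its probe set outside the types that can match several transcripts gave -0.32. The adjusted camera p was 2.8e-15 for type II, 4.7e-16 for type I and 1.5e-15 for airway markers. At an estimated correlation the adjusted p was 0.0037 for type I and 0.061 for both others, so type I markers were the 1 list of 34 that kept its call.

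Of 18 lung endothelial markers 11 fell and 0 rose, with a median of -1.29 (adjusted camera p = 3.0e-11, adjusted p = 0.115 with an estimated correlation). TMEM100, FCN3 and EDNRB fell by 4.64, 3.28 and 2.31. PECAM1, at -0.86, did not reach the threshold of size. This list moved with array width: its median was -2.01 with 17 genes called lower in the 22 pairs with wide arrays only, and -0.35 with 3 called in the 19 pairs with a narrow array. Of 13 alveolar macrophage markers 7 fell and 1 rose, with a median of -1.01 (adjusted camera p = 0.0029, adjusted p = 0.33 with an estimated correlation). CES1, MCEMP1 and FBP1 fell by 2.97, 2.75 and 1.57, while INHBA rose by 1.79.

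Mesothelial and matrix lists were higher at the preset correlation. Of 17 mesothelial markers 10 rose and 1 fell, with a median of 1.17 (adjusted camera p = 0.00091, adjusted p = 0.33 with an estimated correlation). Besides WT1, ITLN1 rose by 2.52 ± 0.52, CALB2, which encodes calretinin, by 2.41 ± 0.30 and UPK1B by 2.31 ± 0.34. GPM6A fell by 3.36 ± 0.29, with a change of -0.18 in its probe set outside the types that can match several transcripts. Of 20 fibrillar collagen and matrix genes 15 rose and 0 fell, with a median of 1.71 (adjusted camera p = 6.2e-12, adjusted p = 0.115 with an estimated correlation). COL11A1, CTHRC1 and THBS2 led this list, and LUM and FN1 were not called at -0.03 and 0.04. Of 16 mesenchymal, sarcomatoid-type genes 5 rose and 0 fell, with a median of 0.35 (adjusted camera p = 0.0047, adjusted p = 0.33 with an estimated correlation). COL5A2, LOX, a collagen cross-linking enzyme, and INHBA rose by 2.38, 2.30 and 1.79.

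Of 16 epithelioid-type mesothelioma genes 5 rose, ITLN1, UPK1B and BNC1 (1.83 ± 0.17) among them, and 3 fell, with CDH1 at -1.86 ± 0.33 and MUC1 at -1.76 ± 0.19; the list median was 0.45 and its adjusted camera p 0.175. Regulators of epithelial-mesenchymal transition and cadherins went both ways, with 4 of 14 higher and 4 lower, a median of 0.13, a mean of -0.16 and an adjusted camera p of 0.98. TWIST1, CDH2 (2.15 ± 0.24), the N-cadherin, and CDH11 (1.26 ± 0.18) rose. EPCAM fell by 4.29 ± 0.34 and ESRP1, an epithelial splicing factor, by 2.89 ± 0.25.

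Cell division lists were higher at the preset correlation. Of 20 spindle checkpoint genes 9 rose and 0 fell, with a median of 0.89 (adjusted camera p = 3.1e-12, adjusted p = 0.074 with an estimated correlation). NDC80 and NUF2, parts of one kinetochore complex, rose by 2.64 and 1.75 ± 0.21, and BUB1B, a checkpoint kinase, by 1.74 ± 0.15 in 40 of 41 pairs. Of 24 kinesin and microtubule genes 9 rose, with a median of 0.76 (adjusted camera p = 8.9e-09, adjusted p = 0.24 with an estimated correlation); NUSAP1, PRC1 and KIF11 rose by 2.14, 1.93 and 1.73. Of 21 DNA replication and S-phase genes 8 rose, with a median of 0.94 (adjusted camera p = 1.3e-13, adjusted p = 0.074 with an estimated correlation), TOP2A, RRM2 (2.07 ± 0.22) and GINS1 (1.92 ± 0.15) among them. The spindle and kinesin lists follow themes for which this study is known, so their calls are not independent evidence. Of 15 folate and nucleotide genes, targets and transporters of antifolate drugs, 4 rose, with a median of 0.41 (adjusted camera p = 0.0022, adjusted p = 0.074 with an estimated correlation). TYMS, thymidylate synthase, rose by 1.78 ± 0.17, GART by 1.19 ± 0.20 and FOLR1 by 1.24 ± 0.16. The probe sets of FOLR1 differed in direction, and their mean gave -0.98. With averaged probe sets TYMS and GART stood at 0.92 and 0.44, under the threshold of size.

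**Figure D2:**
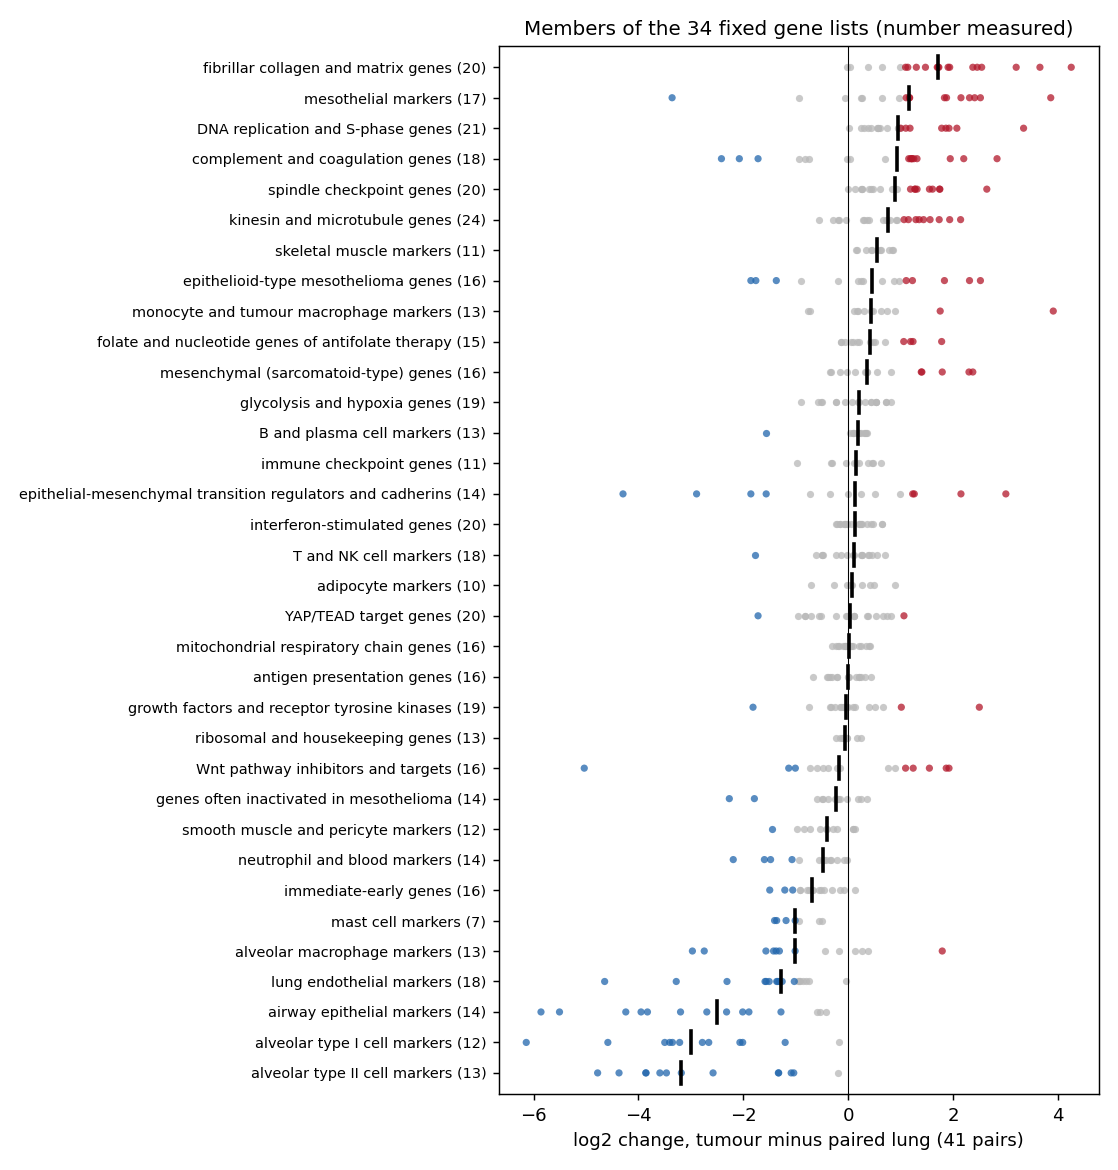
Log2 change in tumour minus paired lung of each measured member of the 34 lists, with the number measured in brackets; red and blue points are called genes, grey points are not called, and black bars are list medians. Medians run from -3.18 for alveolar type II markers to 1.71 for collagen and matrix genes.

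Among immune and blood cell lists, called genes went both ways. Of 13 monocyte and tumour macrophage markers 2 rose, SPP1 and CHI3L1 (1.75 ± 0.32), with a median of 0.43 (adjusted camera p = 0.016, adjusted p = 0.47 with an estimated correlation). Of 7 mast cell markers 4 fell, with a median of -1.01 (adjusted camera p = 2.7e-05, adjusted p = 0.115 with an estimated correlation); KIT, CPA3 and GATA2 fell by 1.40, 1.36 and 1.19, and in the 19 pairs with a narrow array these were -0.63, -0.83 and -0.49, none of them called. Of 14 neutrophil and blood markers 4 fell, with a median of -0.48 (adjusted camera p = 1.4e-06, adjusted p = 0.115 with an estimated correlation); S100A8 fell by 2.19 ± 0.23, PPBP by 1.60 ± 0.17 and HBB by 1.48 ± 0.24. With probe sets that can match several transcripts left out, S100A8 stood at -0.97 and HBB at -0.02. Of 18 T and NK cell markers 1 fell, IL7R by 1.78 ± 0.22, and CD8A was not called at 0.25; the list had a median of 0.10, a mean of -0.05 and an adjusted camera p of 0.95. Of 13 B and plasma cell markers 1 fell, JCHAIN by 1.58 ± 0.32, at an adjusted camera p of 0.175.

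Of 16 immediate-early genes, which respond within minutes to stress, 3 fell, with a median of -0.68 (adjusted camera p = 0.00044, adjusted p = 0.47 with an estimated correlation); KLF4 and ZFP36 fell by 1.21 and 1.06, with the call lost in 2 of 18 and 2 of 19 other settings, and FOSB was 2.82-fold lower. Of 12 smooth muscle and pericyte markers 1 fell, MYH11 by 1.45 ± 0.16, with a median of -0.41 and an adjusted camera p of 0.042 (adjusted p = 0.60 with an estimated correlation). The list's call was lost in 9 of 18 other settings, and MYH11 stood at -0.85 with averaged probe sets. Of 14 measured genes often inactivated in mesothelioma 2 fell, with a median of -0.23 (adjusted camera p = 0.020, adjusted p = 0.24 with an estimated correlation). CDKN2B, a cell-cycle inhibitor, fell by 2.27 ± 0.24 in 38 of 41 pairs and CFAP45, a cilia gene, by 1.79 ± 0.20. Airway markers fell as well (list median -2.51), and whether either fall reflects inactivation in tumour cells was not tested.

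Further lists had called members without a call of the list. Of 18 complement and coagulation genes 9 rose and 3 fell, with a median of 0.92 and an adjusted camera p of 0.31. SERPINE2, CFB and PROCR rose by 2.84, 2.20 and 1.95, CFB with 0.02 in its probe set outside the types that can match several transcripts, and TFPI and CD55 fell by 2.42 and 2.08. Of 16 Wnt inhibitors and targets 5 rose and 3 fell (median -0.18, adjusted camera p = 0.66); WNT2B, SFRP4 and SFRP2 rose by 1.92, 1.87 and 1.55, WIF1 fell by 5.03 and DKK2 by 1.14 ± 0.26. A second probe set of DKK2 passed the adjusted p in the opposite direction, and its change was -0.53 with averaged probe sets and -0.08 in pairs with a narrow array, not called in either. Of 19 growth factors and receptor tyrosine kinases 2 rose, FGF9 by 2.50 ± 0.29 and FGF18 by 1.01 ± 0.22, and ERBB3 fell by 1.82 ± 0.18. For FGF18 1 of 6 probe sets was called, and the call was lost in 4 of 19 other settings. The list had a median of -0.04, a mean of 0.07 and an adjusted camera p of 0.82. Of 20 YAP/TEAD targets 1 rose, IGFBP3 by 1.06 ± 0.19, and 1 fell, F3, the tissue factor gene, by 1.72 ± 0.19 (median 0.03, mean -0.08, adjusted camera p = 0.88).

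No gene was called by limma among 20 interferon-stimulated genes (adjusted camera p = 0.49), 16 antigen presentation genes (0.65), 11 immune checkpoint genes (0.32), 19 glycolysis and hypoxia genes (0.32), 16 respiratory chain genes (0.79), 10 adipocyte markers (0.82), 11 skeletal muscle markers (0.44) or 13 ribosomal and housekeeping genes (0.65). At an unadjusted p under 0.05, these lists held 4 interferon-stimulated, 9 antigen presentation, 7 immune checkpoint, 14 glycolysis, 5 respiratory chain, 5 adipocyte, 0 skeletal muscle and 3 housekeeping genes. At the adjusted p alone, 10 glycolysis genes were higher and 4 lower. Like counts were 3 and 6 for antigen presentation and 4 and 2 for immune checkpoint genes. Interferon-stimulated and respiratory chain genes had 4 and 0 each, adipocyte markers 3 and 1, and housekeeping genes 1 and 2. The threshold of size kept these from a call. Camera called the glycolysis list in 2 of 18 other settings, and the respiratory chain and housekeeping lists in 1 each. CD274, which encodes the ligand PD-L1, stood at -0.98 ± 0.24, just under the threshold of size, and CD276 at 0.63 ± 0.05. In each of the 34 lists, the counts adjusted over the list alone equalled those over all genes. The fry test asks whether a list's genes move one way on balance, without comparing them with other genes. It gave adjusted p-values of 6.4e-06 for mesothelial, 1.2e-09 for matrix and 5.3e-12 for spindle checkpoint genes, and passed 3 lists that camera did not, the epithelioid-type (0.034) and Wnt (0.034) genes and the immune checkpoint genes (0.0074). Its direction was up for the epithelioid-type and immune checkpoint genes and down for the Wnt genes.

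Skeletal muscle transcripts were high in a few samples of either tissue. The list mean exceeded 10 log2 units in 3 of 41 lungs, at 13.7 to 14.1, and in 7 of 55 tumours, at 11.0 to 13.6, against a median of 6.51 in the other 86 samples. In the 3 lungs the alveolar type II list mean was 7.99 to 8.25, at the tumours' median of 8.39 or below, while the other 38 lungs had at least 10.1. In the 32 pairs without such a sample, 1263 genes were called, 1145 of them shared with the 1162.

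**Figure D3:**
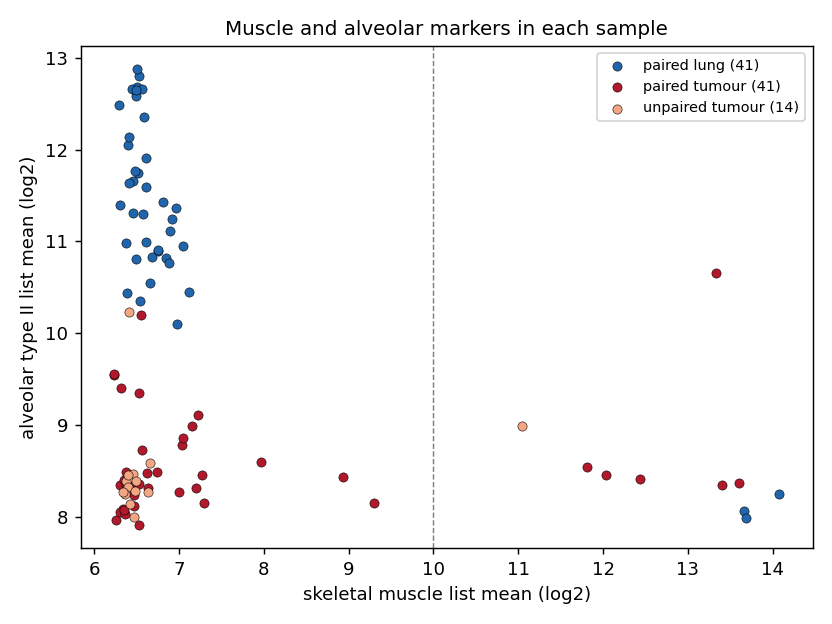
Mean log2 value of the skeletal muscle list against that of the alveolar type II list, 1 point per sample, coloured by group; the dashed line marks 10. In the 10 samples right of the line, 3 are lungs, whose alveolar type II means of 7.99 to 8.25 lie among the tumours.

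The design also asked for differences among tumours, and the first test was of variability. Of 19740 genes, 1846 were more and 545 less variable in 55 tumours than in 41 lungs, and the median SD was 0.431 against 0.361, a ratio of 1.20. That fit took no account of the patients shared by 41 tumours and 41 lungs. With these 41 pairs and the patient number as a block, 3036 genes were called, 2106 of them shared with the 2391 called without it. Lists were counted in the fit of 55 tumours and 41 lungs and not tested. More variable in tumours were 14 of 20 spindle checkpoint genes, 13 of 24 kinesin and microtubule genes, 10 of 21 S-phase genes, 7 of 18 T and NK cell markers, 6 of 13 B and plasma cell markers and 8 of 20 interferon-stimulated genes, with 0 less variable in each list. Less variable were 12 of 18 endothelial, 7 of 14 airway and 3 of 13 alveolar type II markers. Without the 10 samples with skeletal muscle transcripts the alveolar type II list had 1 more and 2 less variable genes, and its median ratio of SDs was 1.03 against 0.693.

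The highest ratios of SDs among called genes were in PURPL, a long non-coding RNA, at 6.97, PTH2R at 5.90, POLR3G at 5.88, ADAMDEC1 at 5.58, DPP10 at 5.08, MMP12, a macrophage elastase, at 4.78, HAPLN1 at 4.62, DSC3, a desmosomal cadherin, at 4.52, ISL1 at 4.50 and CA12 at 4.26. For DSC3 the SDs were 1.61 in tumours and 0.356 in lungs (limma adjusted p = 3.4e-11). The lowest ratios were in ARGLU1-DT (0.0694), ABCA13 (0.0753), RSPH4A, a cilia gene (0.114), MSMB (0.122) and C7orf57 (0.123). For ABCA13 the SDs were 0.155 in tumours and 2.05 in lungs. All 5 had means under 5 log2 units in tumours, near the lower end of the scale, where a lack of signal by itself gives a small SD. PURPL had a mean of 4.34 in lungs, where the same holds for its SD. DPP10, POLR3G, ISL1, ADAMDEC1, PTH2R, DSC3 and MMP12 had lung means of 5.17 to 6.82, under the lung arrays' mean median of 7.39. Their lung SDs were 0.184 to 0.356. No detection limit was set, so low signal in lungs may add to these ratios too.

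Array width entered this comparison. Of 13 ribosomal and housekeeping genes 7 were more variable in tumours, 4 after the 90th percentile was regressed out within each tissue and 1 among wide arrays. The endothelial list had 4 less variable genes after that regression, and 1 more and 2 less variable among wide arrays, with median ratios of 0.951 and 1.08 against 0.579. Of spindle checkpoint genes 13 and 10 were more variable in those settings, 12 and 10 of them among the 14. The like counts were 11 and 10 for kinesin and microtubule genes (10 and 9 among the 13), 8 and 6 for S-phase genes (6 and 4 among the 10), 7 and 5 for T and NK cell markers (6 and 5 among the 7), 9 and 2 for B and plasma cell markers (5 and 2 among the 6) and 14 and 9 for interferon-stimulated genes (7 and 7 among the 8). Of airway markers 10 and 7 were less variable, 7 and 6 of them among the 7. With the 90th percentile regressed out, each of the 15 genes named here kept its call, and 3339 genes were called, 1745 of them shared with the 2391. Among wide arrays, with fewer samples (36 tumours and 23 lungs), 1652 genes were called, 1033 of them shared. PURPL, PTH2R, POLR3G, MMP12, HAPLN1 and ISL1 were not called there, with ratios of at least 4.69 and adjusted p-values of 0.0536 to 0.152.

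The 14 tumours without a lung sample were compared with the 41 paired tumours. By limma, 0 genes were called and 0 passed the adjusted p, with 1143 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.714. With array quality weights 0 genes were called too, with 1343 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0927. Against the 41 lungs, the 14 tumours gave 1358 called genes, 981 of them shared with the 1162 of the pairs (284 higher, 697 lower). Both comparisons use the same lungs. Independent lists would share 8.84 higher and 34.6 lower genes. In 100 simulations of unchanged groups against shared lungs, at most 1 gene was called in the pairs, at most 55 for the 14 tumours, and 0 were shared. With so few genes called in the pairs, these simulations cannot show how far shared lungs raise the overlap. With the lungs divided at random, 21 pairs gave 347 higher and 733 lower genes and the 14 tumours against the other 20 lungs 455 and 868, of which 278 and 639 were shared, where independent lists would share 8.00 and 32.2. This division was chosen after the overlap was seen.

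Across the 55 tumours, 12 relations between list scores were tested, and 11 passed an adjusted permutation p of 0.05. The spindle checkpoint score rose with the S-phase score (r = 0.879, rho = 0.870, permutation p = 1e-05 for each, the smallest that 1e+05 resamples can give). Without the 2 tumours farthest from the median r was 0.865, and it was 0.918 in 36 tumours with wide and 0.837 in 19 with narrow arrays. It also rose with the mesenchymal score (r = 0.591, p = 1e-05, rho = 0.586, p = 4e-05), at 0.535 without 2 tumours, and at 0.547 among wide and 0.661 among narrow arrays. The collagen and mesenchymal scores rose together (r = 0.663, rho = 0.627, p = 1e-05 for each, 0.635 without 2 tumours), with 0.418 among wide and 0.618 among narrow arrays. With the 90th percentile regressed out of each gene it was 0.358 (p = 0.00678, rho = 0.224, p = 0.101).

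The T and NK cell score rose with the antigen presentation score (r = 0.787, rho = 0.741, p = 1e-05 for each), at 0.725 without 2 tumours, 0.923 among wide and 0.718 among narrow arrays. It rose with the spindle checkpoint score (r = 0.605, p = 1e-05, rho = 0.467, p = 0.00035), at 0.538 without 2 tumours and 0.665 among wide arrays, but at 0.212 (permutation p = 0.383) among 19 narrow arrays. In the 41 paired tumours r was 0.560 (rho = 0.347), and 0.329 without 2 of them (rho = 0.242). With interferon-stimulated genes r was 0.430 (p = 0.00105, rho = 0.375, p = 0.00546, 0.376 without 2 tumours), 0.465 among wide and 0.123 among narrow arrays. For each of the 6 relations so far the adjusted p was 0.0018 or less.

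The epithelioid and mesenchymal scores went opposite ways (r = -0.335, p = 0.0123, adjusted p = 0.0164, rho = -0.354, p = 0.00797, -0.323 without 2 tumours), with -0.593 among wide and -0.309 among narrow arrays. The spindle checkpoint score fell with the epithelioid score (r = -0.299, p = 0.0267, adjusted p = 0.032, rho = -0.244, p = 0.0728), at -0.210 without 2 tumours, -0.412 among wide and 0.0597 among narrow arrays. The alveolar type II score rose with the endothelial score (r = 0.442, p = 0.00105, adjusted p = 0.0018, rho = 0.264, p = 0.0522), at 0.331 without 2 tumours, and the relation was -0.0557 among narrow arrays and 0.571 among wide ones. With 2 tumours left out of each set, it was 0.0496 in the 41 paired tumours and 0.149 in the 48 without muscle transcripts. The alveolar type II score fell with the spindle checkpoint score (r = -0.288, p = 0.0315, adjusted p = 0.0344, rho = -0.383, p = 0.00432, -0.255 without 2 tumours), with -0.280 among wide and -0.440 among narrow arrays. The immediate-early score rose with the mesenchymal score over all tumours (r = 0.399, p = 0.00268, adjusted p = 0.00402, rho = 0.340, p = 0.0116, 0.316 without 2 tumours). That relation did not hold within both kinds of array: it was 0.757 among narrow arrays, -0.0736 among wide ones and 0.0947 after the 90th percentile was regressed out. Glycolysis and epithelioid scores did not pass (r = 0.0744, p = 0.588, rho = 0.0377, p = 0.785, with -0.0180 among wide and 0.0229 among narrow arrays).

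The leading component of the 55 tumours held 33.0% of the variance of the 2000 most variable genes and followed array width. Its r with the 90th percentile was 0.961 (rho = 0.839, permutation p = 1e-05 for each), and 0.949 without 2 tumours. For the leading component recomputed within each kind of array, that r was 0.952 among 19 narrow and 0.320 among 36 wide arrays. The 90th percentile itself fell with the 3' minus 5' difference of the GAPDH control probe sets, a measure of RNA quality (r = -0.671, rho = -0.730, p = 1e-05 for each, -0.647 without 2 tumours). For ACTB, a second control, the relation to array width was not tested. Its difference was 4.34 ± 0.66 log2 units in tumours (SD, n = 55), against 1.96 ± 0.75 for GAPDH. Among narrow tumour arrays ACTB ran from 3.93 in tumour 33 to 5.99 in tumour 46. Among wide ones it ran from 3.31 in tumour 28 to 5.90 in tumour 53. The ranges overlapped, and both ends were higher among narrow arrays, the direction that GAPDH took. The genes with the highest correlation with the component were PRKAA1, GTF2A1, SPTLC1, BMPR2, TARDBP, SCARB2, ZBTB11 and UXS1, at 0.942 to 0.957. Those with the lowest were FBXL19, TFAP4, ZNF77, FOXH1, TMEM92-AS1, HBZ, HOXB1 and KRT25, at -0.956 to -0.962. Of the lists, ribosomal and housekeeping genes had the highest r, 0.938 (rho = 0.760, adjusted p = 2.62e-05).

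**Figure D4:**
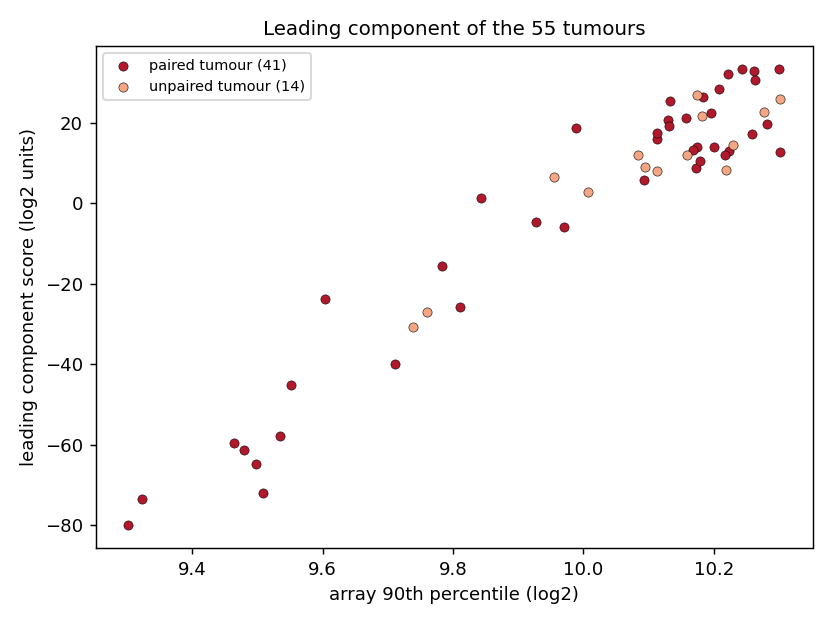
Score of each of the 55 tumours on the leading component (log2 units) against the 90th percentile of its array (log2), with paired and further tumours in different colours. Scores rise with array width (r = 0.961), and paired and further tumours overlap.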

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

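The tests of exchanged labels, of the GAPDH difference, of muscle in the leading component, of array width along the patient numbers, of array width behind the T cell relation and of array width behind 1 split of the tumours were chosen after the results were seen. Among 13522 probe sets outside the gene comparison, which have several gene symbols or no name here, 115 were higher and 141 lower in tumour than in paired lung by the thresholds used for genes. They include 25 higher and 40 lower probe sets with several symbols. The largest rise was 2.78 and the largest fall -5.47 log2 units, and they stand here as signal in data that the comparisons of named genes do not use.

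Skeletal muscle genes stood out in 3 lungs and 7 tumours. Of 12 other skeletal muscle genes, outside the fixed list, 9 of the 10 samples had 9 to 12 at least 2 log2 units above the median of their tissue, while the other 86 samples had at most 2. The remaining tumour had 5, which met the bound set in advance against muscle tissue, and that bound was set aside after this was seen because it left no room for a smaller share of muscle: this tumour had the lowest list mean of the 10, 11.0, and 10 of the genes were at least 1 unit up, against at most 5 in the other 86 samples. An exchange of lung and tumour within the pairs of the 3 lungs is argued against, since the tumours of those pairs had alveolar type II means of at most 8.49 and the other 38 lungs at least 10.1. Muscle of the chest wall in the sampled piece may therefore account for these samples, while a wrong label from outside the pairs stays open for the 3 lungs, and no biological explanation was tested.

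The leading component of the tumours followed array width. Slopes of genes on the 90th percentile, freed of their trend with mean level, correlated at 0.767 between tumours and lungs (across genes, which are not independent replicates), so the axis was shared by both tissues. The GAPDH 3' minus 5' difference fell with array width in the 41 lungs too (r = -0.537, rho = -0.676, permutation p = 0.00034 and 1e-05, -0.518 without 2 lungs). The test of muscle first set, the relation of its score to the component (r = -0.166, p = 0.229, rho = -0.562, p = 3e-05), gave a split answer and was replaced after it was seen by leaving those tumours out. The component then held 36.6% of the variance in 48 tumours, which argues against muscle as its source. Array width was also shared in part by the lung and tumour of a pair (r = 0.685). The mean absolute difference in the 90th percentile between neighbouring patient numbers was 0.19 log2 units in lungs, against 0.28 with shuffled numbers (one-sided permutation p = 0.00063), and 0.28 against 0.33 in paired tumours (p = 0.0547). In lungs array width thus followed the order of the patient numbers, which handling in batches along them would give. The paired tumours went the same way, with a permutation p just above the limit of 0.05 set for both tissues. A property of the patients unrelated to their numbers would not give this order in lungs. How the numbers were given was not examined here, so a property that follows the numbers cannot be told apart from handling. In lungs the 3' minus 5' differences were 2.01 ± 0.49 log2 units for GAPDH and 4.09 ± 0.61 for ACTB (SD, n = 41). The relation of ACTB to array width was not tested in either tissue. RNA quality, read here from GAPDH alone, or another step shared by both tissues is a possible explanation, and no biological explanation was tested.

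The T and NK cell score rose with the spindle checkpoint score across tumours. With array width regressed out r was 0.615, with the mesenchymal and epithelioid scores also held fixed it was 0.494 (permutation p = 0.00015), and with 6 scores of matrix, muscle, fat, vessel and lung held fixed instead it was 0.636 (p = 1e-05, the smallest possible). These values argue against each of the 3 as the whole source. The relation was 0.212 among 19 narrow arrays, and its difference from the 0.665 among wide arrays was not tested. In the 41 paired tumours it was 0.560, and 0.329 without 2 of them, with array width not regressed out. Dividing lymphocytes and faster division of tumour cells in inflamed tumours may both give such a relation, and bulk tissue cannot separate them; no biological explanation was tested.

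Chance was tested by regrouping the samples 100 times for each comparison, the real grouping included. For tumour against paired lung, labels were exchanged within pairs, and 1 of 100 splits gave as many genes, the real one with 1162, against at most 0 in the others. For variability, 1 of 100 did, the real one with 2391, against at most 66. Each real count was the highest of its 100 splits, and 1 of 100 is the smallest share that 100 splits can give. For variability the regrouping did not keep the lung and tumour of a patient together. For the 14 against 41 tumours the real count was 0, which every split reaches, so the count of splits decides nothing there. Of the 99 other splits 1 called 626 genes. It had the largest difference in array width of the 99, with a mean 90th percentile 0.29 log2 units lower in its 14 tumours than in its 41, and called 0 genes with the 90th percentile as a covariate, which points to array width as the structure it followed.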

How the results depend on the processing

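Settings that concern array width, muscle, the pairs that did not match and the filter at 7 were chosen after the data were seen. Under 19 of 20 alternatives to the paired fit, 776 to 1358 genes were called. The fit with no replicate block called 1162 genes, the same 1162 as with the block, and changed no call of a named gene; with an estimated correlation it called 6 lists against 1 with the block. With treat, 432 passed (90 higher, 342 lower). With the mean of a gene's probe sets 562 were lower, and with 14 unpaired tumours against the lungs 549 were higher. The share of called genes higher in tumour was 27.4%, 27.8% after quantile normalization, 26.7% after median centring, and 32.8% in pairs with wide arrays only against 21.7% in pairs with a narrow array. Across all settings this share ran from 20.8% with treat to 40.4% for the 14 unpaired tumours against the lungs. Of 1578 values of the 84 named genes, 1544 kept direction and call, 33 lost the call and 1 reversed, FOLR1 with averaged probe sets (-0.98), whose probe sets differ in direction. With probe sets of the types that can match several transcripts left out, 18 of the 84 genes, WT1 and SPP1 among them, had no value. Of 612 list results 589 were kept, 14 lost and 9 gained a call; the count of called lists was 16 to 20, and of 18 settings the smooth muscle call was lost in 9, that of genes often inactivated in 3 and that of monocyte and tumour macrophage markers in 2. More variable genes numbered 2778 with deviations from the mean and 1194 among wide arrays, and of 142 ratios of named genes 136 kept the call and 6 lost it. No setting called a gene between unpaired and paired tumours.

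Across tumours, 7 of 12 relations passed in the 41 paired tumours and 5 in narrow arrays, where fewer samples were tested. In the 41 tumours, r was -0.290 for epithelioid with mesenchymal, -0.327 for spindle checkpoint with epithelioid, 0.313 for T and NK cell with interferon and -0.184 for alveolar type II with spindle checkpoint scores. For immediate-early with mesenchymal scores r was 0.143 after quantile normalization, 0.0947 with width regressed out and -0.0736 among wide arrays, where alveolar type II with spindle checkpoint scores had -0.280. Among narrow arrays r was -0.309 for epithelioid with mesenchymal, 0.0597 for spindle checkpoint with epithelioid, 0.123 for T and NK cell with interferon, 0.212 for T and NK cell with spindle checkpoint, -0.0557 for alveolar type II with endothelial and -0.440 for alveolar type II with spindle checkpoint scores. Without muscle-containing tumours, epithelioid with mesenchymal had -0.287. The leading component held 39.5% in paired tumours, 27.4% after quantile normalization, 16.1% with width regressed out, 21.1% among wide and 39.5% among narrow arrays. After quantile normalization the component still followed the original array width, at r = 0.931 against 0.961 in the main setting. That step thus lowered the share but left the relation to width. Beyond what is stated, the cause was not tested. The setting with no filter moved nothing. No background measure was used, so low probe sets limit small changes.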

Other observations

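With array width regressed out of each gene, the leading component of the 55 tumours followed immune and cell division scores. This setting, and the one without muscle-containing tumours, were chosen after the data were seen. The leading component then held 16.1% of the variance. Its highest correlations were with ANKRD22, NOD2, an intracellular sensor of bacteria, PSTPIP1, GBP5, THEMIS, a T cell gene, GPR84, IL4I1 and NKG7, at 0.804 to 0.851. The lowest were with FRY, GHR, RC3H1, OGN, RGS5, a pericyte marker, MGP, EGR1 and NFIA, at -0.737 to -0.787. Of the 34 list scores, immune checkpoint genes had r = 0.813 (rho = 0.699), T and NK cell markers 0.743 (rho = 0.664), spindle checkpoint genes 0.693 (rho = 0.623) and folate genes 0.683 (rho = 0.619), each with an adjusted p of 3.78e-05. Immediate-early genes had -0.618 (rho = -0.591), Wnt genes -0.587 (rho = -0.581), smooth muscle markers -0.586 (rho = -0.600) and collagen genes -0.509 (rho = -0.456). Skeletal muscle markers had -0.486 (rho = -0.222, adjusted p = 0.00072), and the 7 tumours with skeletal muscle transcripts all lay below the median of the component, 3 of them lowest. Without these 7 the component held 17.8% of the variance, and immune checkpoint genes had r = 0.876, T and NK cell markers 0.814, spindle checkpoint genes 0.735 and folate genes 0.751 over 48 tumours, while skeletal muscle markers had 0.0436 (adjusted p = 0.777) and smooth muscle markers -0.362. Over these 48, mesothelial markers had -0.546, epithelioid-type genes -0.544 and mesenchymal genes 0.393 (adjusted permutation p = 0.000185, 0.000209 and 0.00916). Over all 55 they had -0.319, -0.251 and 0.243 (adjusted permutation p = 0.0257, 0.0869 and 0.0946). B and plasma cell markers did not pass with the component of the 55 tumours (r = 0.0428, adjusted p = 0.762), nor with the spindle checkpoint score (r = 0.0742, permutation p = 0.591, rho = 0.0294, p = 0.831, -0.0824 without 2 tumours). Monocyte and tumour macrophage markers rose with the spindle checkpoint score (r = 0.325, permutation p = 0.0158, adjusted p = 0.0203 over 9 relations, rho = 0.354, p = 0.00857, 0.476 without 2 tumours).

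The hypothesis that tumours express less from chromosome 22, which is often lost in mesothelioma, was set before its values were seen. The median change of 460 genes on it was 0.00790 log2 units, rank 7 of 23 from the lowest, with an adjusted camera p of 0.743 and 0.970 at an estimated correlation, so the predicted fall was not seen, while the rank above 8 set as the bound against it was not reached either. With array width as a covariate its median was -0.0142, rank 4 of 23, below 0 as predicted and outside the 3 lowest that were predicted; no list test was run in that fit. On this chromosome 12 of the 460 genes were called lower and 1 higher. Of all genes tested 4.28% were called lower and 1.61% higher, so calls in either direction were not in excess there. A call needs a change of at least 1 log2 unit, so these counts cannot show a smaller fall across the chromosome and do not decide the prediction. The lowest median, -0.01, was that of chromosome 14 and the highest, 0.05, that of chromosome 7.

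MTAP and CDKN2B lie close together on the short arm of chromosome 9, and joint loss in part of the tumours was predicted to give r above 0.4 in tumours and above that in lungs. With array width regressed out r was 0.516 over 55 tumours (rho = 0.612, permutation p = 7e-05 and 1e-05, 0.548 without 2 tumours). It was 0.388 over 41 lungs (rho = 0.440, permutation p = 0.0121 and 0.00434), and the difference of 0.128 gave a permutation p of 0.337. Both r values meet what was predicted, and the demand that the difference itself pass was added after they were seen. Joint loss may contribute, but since the lungs show a like relation the 2 sources cannot be told apart from these values.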
